A study of Gallus gallus with 5 samples.

How the data were processed

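Total RNA of DT40 cells, a chicken B cell line with frequent homologous recombination, was measured on 5 Affymetrix Chicken Genome arrays: 2 of wild-type cells (WT), 1 of cells labelled as a deletion of the linker histone variant H1L and 2 of cells labelled as a deletion of the variant H1R. Groups and replicate numbers were taken from the sample titles. The labels do not say whether replicates came from separate cultures or clones, so p-values measure only the spread between these arrays, which may be technical. The descriptions carry a date code that places replicate 1 of WT and of H1R on a first day and replicate 2 of both, with the array labelled H1L, on a second day.

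The deposited values are probe set signal intensity on a linear scale, made by the authors with GCOS, per the submitters' processing notes. The GCOS version, the scaling target and the detection calls were not given in the sources used here. The 2% trimmed means of the arrays lay between 120.8 and 154.5, so the arrays had not all been scaled to 1 target over all probe sets, and the scale between arrays is in this sense unknown. The values were analysed as deposited, and scaling was varied as an alternative. The number of arrays limits the precision.

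The 96 Affymetrix control probe sets were left out, which left 38439. Of these, 27168 had 1 gene symbol in the platform's probe table, 177 had several and 11094 had none. A gene was named only from a probe set with 1 symbol, and 26853 probe sets were matched through their gene number to the RefSeq genes of the GRCg7b assembly, which gave the chromosome. Values were tested as log2(signal + 6), where 6 is the 25th percentile of all signals, so fold changes of dim probe sets are understated. Probe sets with a mean signal over the 5 arrays above 13.4, the 40th percentile, were tested, which gave 23053 probe sets and 9962 named genes. Where only some probe sets of a gene named among the largest changes against WT passed, their count is given.

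A linear model with 1 term per group was fitted to all 5 arrays with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a trend), and p-values were adjusted by the Benjamini-Hochberg method within a comparison, with 0.05 as threshold. The arrays shared 1 estimate of the spread, with 2 residual and 6.04 prior degrees of freedom. The array labelled H1L has no replicate, and its tests assume that it varies like the WT and H1R arrays. Errors given with ± are standard errors of the log2 fold change. The 3 comparisons were H1R against WT, H1L against WT and H1L against H1R. On simulated data with 200 changed probe sets among 23053, over 5 runs, the test of H1R against WT recovered 76% of 4-fold and 100% of 16-fold changes with 7.85% false calls among all calls. For H1L against WT it recovered 50.8% and 99.8%, with 9.17% false calls. Both shares of false calls exceed the threshold of 0.05.

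WT and H1R arrays of the same number share a day by their date code, and their deviations from the group means correlated at 0.192 across probe sets, or 0.188 after quantile normalization. The numbers were therefore taken to pair the arrays, and a fit with the day as block was run beside the fit without it. The fit with the block had 1 residual and 8.32 prior degrees of freedom, and no fold printed below comes from it. The 2 arrays most alike in value shared 0.856% of identical signals, so no array repeated another.

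The detection calls were not used here. As a bound on background, the highest signal among 23 control probe sets without a target in chicken RNA was taken for each array. It was 29.2 and 21.4 for the WT arrays, 23 for the array labelled H1L, and 18 and 33.6 for the H1R arrays. Where all arrays of a group lay at or below it, the fold is given as a lower bound, from the mean log2 signal of the bright group and, for the dim group, the mean log2 of the higher of the limit and the signal on each array. The bound is that of the probe set named, and other probe sets of the gene can differ. It was chosen after the data were seen.

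Before the data were examined, 20 gene lists and a rule for naming genes were fixed. The rule took the 12 largest rises and falls past the threshold for each deletion against WT, among probe sets with 1 symbol that is not a provisional one starting with LOC, with the same sign on both days for H1R, and 5 each way for H1L against H1R, filled with changes at an unadjusted p under 0.01 where too few passed. Linker histone probe sets and list members past the threshold could also be named. Lists were tested with camera at a preset correlation of 0.01 on 1 probe set per gene, with an estimated correlation and fry as alternatives. The estimate rests on 2 residual degrees of freedom. With it, camera gave an adjusted p of at least 0.958 for every list in every comparison, so this value does not tell lists apart. Of the 20 lists, 18 could be tested. The linker histone list held 2 tested genes and the retroviral list held 0, since the probe table used here has no gene titles.

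The comparison of both deletions shares its WT arrays, so 20 data sets of unchanged groups that share their WT arrays were simulated for the value given by chance. Shifts of whole chromosomes were examined after they had been seen in the data. They used 5483 genes with a known chromosome and a mean signal of at least 100, and the 29 chromosomes with at least 20 such genes were examined. A chromosome was called shifted where the median log2 ratio of its genes, relative to the median gene, was at least 0.25 in size and farther from 0 than in all 10000 random gene lists matched on signal. These limits were also set after the data were seen.

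Alternatives were the day as block, quantile normalization, median scaling, a pseudocount of 1.5 or of 24, no filter and a stricter filter at the 60th percentile, eBayes without a trend and with robust estimation, the WT and H1R arrays alone, and each array left out in turn. The removal of chromosome medians was added after the data were seen.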

Results

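Gene expression was measured in chicken DT40 cells, a B cell line, on 5 Affymetrix arrays: 2 of WT cells, 1 labelled as a deletion of the linker histone variant H1L and 2 labelled as deletions of the variant H1R. Linker histones bind the DNA between nucleosomes, and the series asked which genes depend on single H1 variants. Median signals were 19.9 and 20.7 on the WT arrays, 19.3 on the array labelled H1L, and 19.9 and 22.4 on the H1R arrays. The share of probe sets above the background limit was 41% and 49.2% for WT, 45.8% for the array labelled H1L, and 52.5% and 41.2% for H1R. The ratio of the 3' to the 5' actin probe set, a sign of RNA quality, was 2.81 for WT and 3.87 for H1R on the first day, and 2.02 for WT, 2.01 for the array labelled H1L and 2.25 for H1R on the second day. Correlations of log2 signals between arrays lay between 0.921 and 0.959, and those of the WT replicates (0.956) and of the H1R replicates (0.952) were below the highest, which joined the array labelled H1L and replicate 2 of H1R.

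The linker histone probe sets were examined first, since they bear on the labels. HIST1H111L gave signals of 1320 and 2034.8 in WT, 2295.3 on the array labelled H1L, and 981.8 and 2372 in H1R. It was not lowered on the array labelled H1L (log2 fold change against WT 0.48 ± 0.51, limma adjusted p = 0.95). HIST1H111R lay near background, with 36.1 and 39.4 in WT, 42.2 on the array labelled H1L, and 28.9 and 7 in H1R (log2 fold change of H1R against WT -1.04 ± 0.51, limma adjusted p = 0.57). The labels do not state that H1L and H1R are these genes, and the probe sets may lie outside the deleted part or read other, nearly identical H1 transcripts, so neither checks the labels. On replicate 1 of H1R, HIST1H111R was above that array's background limit of 18 and close to WT. For this reason the text writes of the array labelled H1L, and H1R stands for the arrays labelled H1R. Every direction drawn from either rests on the labels.

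Against WT, the arrays labelled H1R gave higher signals of CPNE8, a copine that binds phospholipid, KCNMA1, the pore subunit of the BK potassium channel, PPDPF, HSPA12A, a distant member of the HSP70 family, and SLA, a Src-like adaptor. CPNE8 rose from 6.8 and 0.8 to 858.7 and 769.6, at least 32.5-fold, and HSPA12A from 14.4 and 12.2 to 1295.2 and 1018.5, at least 45.9-fold. The largest falls of genes with a settled symbol were those of KCNMB1, a regulatory subunit of the same channel (at least 24.3-fold lower), TNFSF13B, a survival cytokine of B cells, and FABP5, a fatty acid binding protein (at least 32.3-fold lower). TNFSF13B fell from 1014.7 and 1775.5 to 20.4 and 16.1, a log2 fold change of -5.80 ± 0.37. In all, 269 of 23053 probe sets changed with limma (Benjamini-Hochberg), 134 higher and 135 lower, covering 88 and 95 named genes, and 2357 had an unadjusted p under 0.05 where 1153 were expected by chance.

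Among the other genes that rose were TPD52L1 (at least 27.3-fold), DCX, a microtubule protein of migrating neurons (at least 18.5-fold), ARRDC1 (at least 28.4-fold), LGALS1B, a galectin (at least 24.6-fold), and CA3B, a carbonic anhydrase (at least 16.6-fold). SLC39A8, a zinc transporter, rose by a log2 fold change of 5.10 ± 0.63 and VLDLR, a lipoprotein receptor, by 4.96 ± 0.72. Among the other falls were POPDC3 (at least 9.29-fold lower), THSD7A (at least 19.1-fold lower), PINLYP (at least 15.8-fold lower), PRKCH, a protein kinase C (at least 8.49-fold lower), TRBV6-5 (at least 15.1-fold lower), CACFD1 (at least 7.82-fold lower) and ELOVL7, a fatty acid elongase (at least 13.2-fold lower). LITAF had a log2 fold change of -4.99 ± 0.62 and BMERB1 of -4.76 ± 0.40. The 12 rises and the 12 falls named here had limma adjusted p-values between 9e-04 and 0.018. Of the probe sets of a gene, 1 of 3 passed for LGALS1B, whose others read at most 30.7 in H1R and did not show its rise. The count was 1 of 4 for DCX (others at most 95.9 in H1R), 1 of 2 for ARRDC1 (other 5.8 and 59 in H1R) and 1 of 3 for PRKCH (others at least 1.85-fold and 1.59-fold lower). It was 2 of 3 for SLC39A8 and CACFD1, and 3 of 4 for KCNMA1, THSD7A and POPDC3. CACFD1 had its other probe set at -0.90. A called probe set of THSD7A, above background in replicate 1 of H1R, had -3.65 ± 0.43. With the day as block, limma called 854 probe sets, 498 higher and 356 lower, which included all 269. The count fell to 81 without replicate 1 of WT and to 149 without replicate 2 of WT, and SLC39A8 and LITAF then lost their calls without the former and LITAF also without the latter.

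Of 38 tested B cell genes, 1 rose and 2 fell in H1R (limma, over all probe sets), and 1 rose and 5 fell when adjusted over the list alone. CXCR4, a chemokine receptor, rose by a log2 fold change of 1.79 ± 0.31, IRF4, a transcription factor of B and plasma cells, had one of -2.25 ± 0.25, and CD79B, a signalling chain of the B cell receptor, one of -1.45 ± 0.22. As a list, B cell genes did not pass (camera adjusted p = 0.216), and their median log2 fold change of 0.0755 and mean of -0.0902 differed in sign. They were called lower without replicate 1 of WT (median -0.33, camera adjusted p = 0.00229), with chromosome medians removed (0.0428) and with probe sets averaged (0.0443). With an estimated correlation they were not called (camera adjusted p = 0.984 with an estimated correlation). Members of the other cell type lists also moved, which does not assign them to 1 cell type. CD5 in the list of 8 T cell genes rose by a log2 fold change of 2.88 ± 0.37. MMP9 among 12 myeloid genes rose by 2.81 ± 0.45, and MMP2 among 10 fibroblast genes at least 12.1-fold. Each was the 1 member of its list past the threshold over all probe sets. Adjusted over the list alone, the T cell list held 1 rise and 1 fall, the myeloid list 1 rise and the fibroblast list 2 rises. TNFRSF1B, a receptor of tumour necrosis factor, fell among 34 survival genes (log2 fold change -2.95 ± 0.42), and adjusted over the list alone 2 members fell. IRF4 was also the 1 of 9 plasma cell genes past the threshold, and adjusted over the list alone 1 plasma cell gene was higher and 1 lower. As lists, the plasma cell, T cell, myeloid, fibroblast and survival genes did not pass (camera adjusted p = 0.457, 0.655, 0.457, 0.658 and 0.275).

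The 25 tested cholesterol and fatty acid synthesis genes were lower as a list in H1R, with a median log2 fold change of -0.227 against 0.118 for all genes (camera adjusted p = 0.0307). The list's call was lost with an estimated correlation (camera adjusted p = 0.984 with an estimated correlation), and without replicate 1 of WT (camera adjusted p = 0.673) or replicate 2 of H1R (camera adjusted p = 0.474). None of its genes passed alone, whether over all probe sets or adjusted over the list alone, and ACLY at -0.90 ± 0.32 and FADS1, at least 1.32-fold higher, differed most. Core histone, chromatin regulator, DNA repair, erythroid, antigen presentation, interferon, cell cycle, glycolysis, heat shock, ribosomal protein and oxidative phosphorylation lists were not called, with camera adjusted p-values of 0.829, 0.968, 0.829, 0.799, 0.375, 0.58, 0.375, 0.799, 0.709, 0.275 and 0.272, and 0 of their members passed over all probe sets. Oxidative phosphorylation genes were called lower after quantile normalization (camera adjusted p = 0.0181) and ribosomal protein genes after median scaling (camera adjusted p = 0.0112). Neither was called with an estimated correlation (camera adjusted p = 0.984 with an estimated correlation). Adjusted over the list alone, 2 heat shock genes were higher and 1 lower, and 1 erythroid gene was lower.

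**Figure D1:**
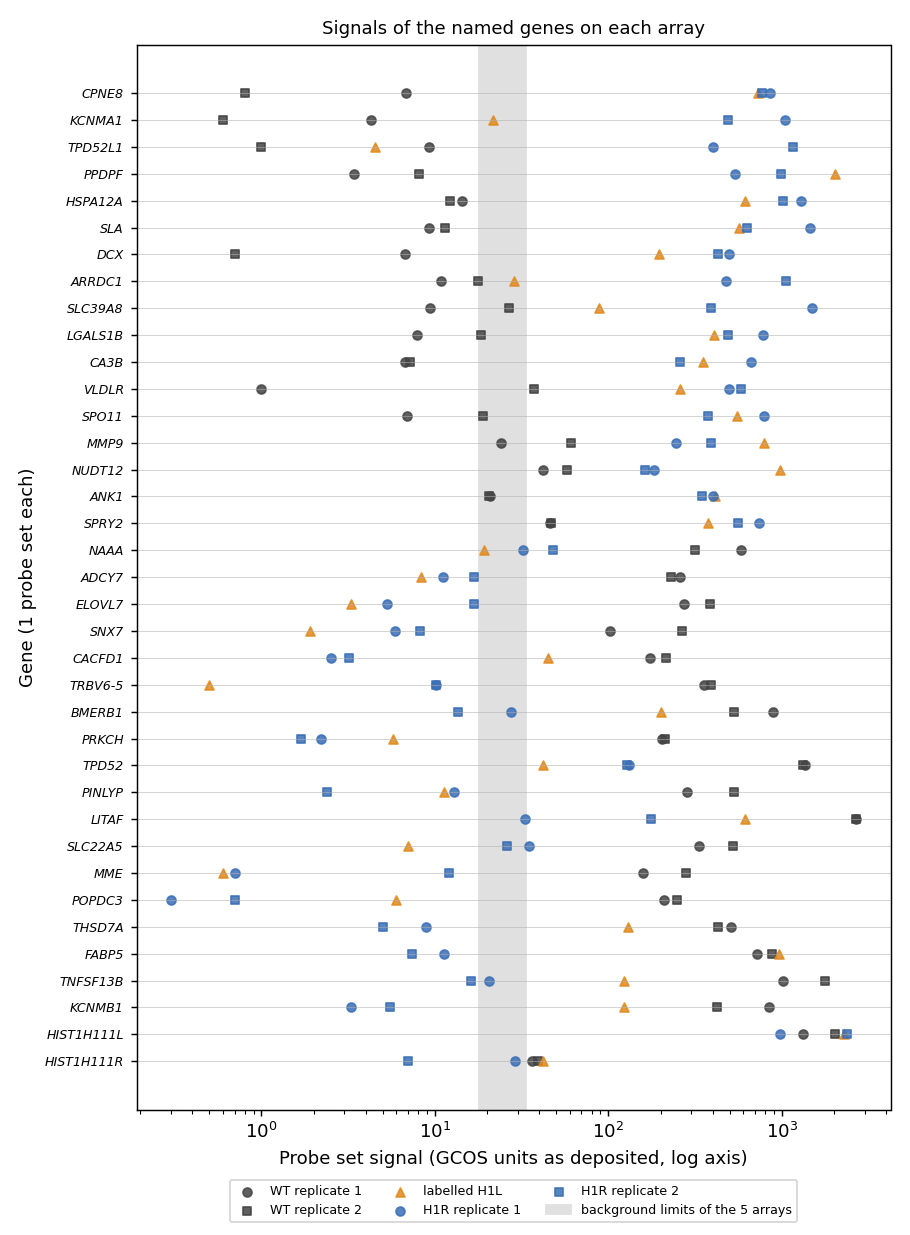
Probe set signals of the named genes (log axis, GCOS units as deposited), 1 point per array: grey for WT, orange for the array labelled H1L, blue for H1R, circles for replicate 1 and squares for replicate 2, with the grey band spanning the background limits of the 5 arrays (18 to 33.6). FABP5 read 720.2 and 877.8 in WT and 962.6 on the array labelled H1L, but 11.3 and 7.4 in H1R.

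On the array labelled H1L, PPDPF reached 2021.2 against 3.4 and 8.1 in WT, at least 80.9-fold higher, and CPNE8 reached 728, at least 29.1-fold higher. SLA (at least 22.6-fold), HSPA12A (at least 24.6-fold), SPO11, which makes meiotic DNA breaks (at least 21.9-fold), and MMP9 (log2 fold change 4.15 ± 0.55) were also higher. The largest falls of genes with a settled symbol were those of TRBV6-5 (at least 16.2-fold lower), ELOVL7 (at least 14.1-fold), MME, a membrane peptidase known as CD10 (at least 9.13-fold), and SLC22A5, a carnitine transporter (at least 18.1-fold). TPD52 fell from 1353.4 and 1325 to 42.1, a log2 fold change of -4.81 ± 0.36. With limma, 46 of 23053 probe sets changed, 21 higher and 25 lower, covering 15 and 21 named genes, and 1589 had an unadjusted p under 0.05 where 1153 were expected by chance.

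CA3B (at least 14-fold), LGALS1B (at least 16.2-fold), DCX (at least 7.79-fold) and ANK1, a membrane skeleton protein (at least 16.4-fold), were among the other rises, with NUDT12 (log2 fold change 4.14 ± 0.39) and SPRY2, an inhibitor of receptor tyrosine kinase signalling (2.87 ± 0.38). PINLYP (at least 16.9-fold lower), SNX7 (at least 7.16-fold lower), POPDC3 (at least 9.93-fold lower), PRKCH (at least 9.07-fold lower), ADCY7, an adenylyl cyclase (at least 10.6-fold lower), and NAAA (at least 18.7-fold lower) fell as well. TNFSF13B, in its brightest probe set, fell from 1014.7 and 1775.5 to 122.5 (log2 fold change -3.39 ± 0.45). Of the probe sets of a gene, 1 of 6 passed for ANK1, whose others lay between a log2 fold change of -0.62 and at least 2.72-fold higher. The count was 1 of 3 for ADCY7, whose others were near background and at -0.67, and 1 of 2 for NAAA, whose other was at -0.48. LGALS1B passed in 1 of 3, with the others at signals of 23.4 and 21.8. Probe sets passed in 1 of 4 for DCX, 2 of 4 for POPDC3, 1 of 3 for TPD52 and PRKCH, 2 of 3 for SLA and TNFSF13B, and 1 of 2 for MME and SLC22A5. Limma adjusted p-values of these named genes lay between 0.0049 and 0.045. All of these values rest on 1 array, and the count of 46 became 117 with the day as block (48 higher, 69 lower), 4 without a filter on dim probe sets, and 0 with limma's eBayes without a trend, where 1568 had an unadjusted p under 0.05. It was 2 without replicate 1 of WT, where PPDPF and CPNE8 kept their calls, 28 without replicate 2 of WT, 122 without replicate 1 of H1R and 126 without replicate 2 of H1R.

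MMP9 was the 1 member past the threshold over all probe sets in the 18 lists tested for the array labelled H1L. Adjusted over the list alone, VAV3 and IRF4 were lower in the B cell list, and IRF4 (log2 fold change -1.95 ± 0.31), CD5 (2.90 ± 0.45), TNFRSF1B (at least 9.15-fold lower), LIG4, a ligase of DNA end joining (-2.37 ± 0.37), and EPB41 (-1.79 ± 0.31) passed in their lists, without passing over all probe sets. Cholesterol and fatty acid synthesis genes were lower as a list (median log2 fold change -0.538, camera adjusted p = 0.00195, and adjusted p = 0.958 with an estimated correlation), with NSDHL at -1.29 ± 0.35 and MSMO1 at -0.98 ± 0.28. Heat shock genes (median -0.327, camera adjusted p = 0.0434) and ribosomal protein genes (median -0.129, camera adjusted p = 0.0326) were also lower as lists, and 0 members of these 3 lists passed alone. For both, camera gave an adjusted p = 0.958 with an estimated correlation. After quantile normalization the ribosomal median was -0.00449 and the direction of its test turned (camera adjusted p = 0.998), and the heat shock list no longer passed (0.215). Without replicate 1 of WT the cholesterol and ribosomal lists gave camera adjusted p-values of 0.215 and 0.323, and without replicate 2 of WT the heat shock list gave 0.123. With the day as block, chromatin regulator (camera adjusted p = 0.0326) and oxidative phosphorylation genes (0.0132) were lower as lists too. For both, the fit without the block gave camera adjusted p = 0.958 with an estimated correlation. The other lists, core histone, DNA repair, B cell, plasma cell, T cell, myeloid, erythroid, fibroblast, antigen presentation, interferon, cell cycle, survival and glycolysis genes, were not called (camera adjusted p between 0.136 and 0.921). Of these, cell cycle genes were called higher after quantile normalization (camera adjusted p = 0.0225) and without replicate 2 of WT (0.0184), and plasma cell genes lower without replicate 2 of WT (0.0342). Chromatin regulator genes were also called lower without replicate 1 of WT (camera adjusted p = 0.0244). With all arrays, each of these had a camera adjusted p = 0.958 with an estimated correlation.

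FABP5 differed between the labels: it read 962.6 on the array labelled H1L and 11.3 and 7.4 in H1R, at least 39.1-fold higher (fitted log2 fold change 5.99 ± 0.39, or 6.14 relative to the median probe set, limma adjusted p = 0.0075). It was the 1 probe set of 23053 past the threshold in this direct comparison, and 1278 had an unadjusted p under 0.05. NALCN (at least 39.3-fold), DPYSL3 (at least 3.83-fold), CACNA2D1 (relative log2 fold change 4.62) and COTL1 (3.94) read higher on the array labelled H1L. TPD52L1 (at least 29.7-fold), KCNMA1 (at least 9.12-fold), MMP2 (at least 13.1-fold), ARRDC1 (relative log2 fold change -4.23) and KCNJ15 (-4.09) read lower. None of these 9 passed, with limma adjusted p-values from 0.098 to 0.77. With the day as block NALCN (limma adjusted p = 0.042), TPD52L1 (0.018), KCNMA1 (0.042), ARRDC1 (0.0039), KCNJ15 (0.0074) and MMP2 (0.026) did, and MMP2 also passed when adjusted over the list alone, as the 1 fibroblast gene. The median log2 fold change of all probe sets was -0.146 on the deposited scale and -0.00433 after quantile normalization. The count was 31 with the day as block, 18 higher and 13 lower, 0 without replicate 1 of WT, which left the fold of FABP5 at 5.99, 9 without replicate 1 of H1R and 32 without replicate 2 of H1R. None of the 18 gene lists was called, the lowest camera adjusted p being 0.0793 for B cell genes (median log2 fold change 0.0482). These were called higher after quantile normalization (camera adjusted p = 0.0136), removal of chromosome medians (0.0387), averaging of probe sets (0.00461) and without replicate 1 (0.0461) or 2 (0.0479) of WT. They were not called with the day as block (camera adjusted p = 0.248) or with an estimated correlation (adjusted p = 0.992 with an estimated correlation). Chromatin regulator genes were called lower with the day as block (camera adjusted p = 0.0422), and the fit without it gave adjusted p = 0.992 with an estimated correlation.

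By size alone, 2122 probe sets differed at least 1 log2 unit between H1R and WT (1156 higher, 966 lower). Of these, 1072 differed by at least 1 log2 unit the same way on each of the 2 days. For the group means, the balance of higher and lower turned after quantile normalization (1013 higher, 1072 lower) and median scaling (1030 higher, 1055 lower). By the same measure, 2386 differed between the array labelled H1L and WT (961 higher, 1425 lower). Between the array labelled H1L and H1R 720 were higher and 1379 lower, against 976 and 1115 after quantile normalization. The 2 WT arrays differed from each other in 2776 probe sets by this measure and the 2 H1R arrays in 3196. Single arrays carry more noise than means of 2. Among 9416 probe sets with a mean signal of at least 100, single WT and H1R arrays differed 4-fold in 185 to 232, the WT arrays in 33 and the H1R arrays in 59.

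Both labelled deletions were compared with the same WT arrays. Of the 46 probe sets called for the array labelled H1L, 44 were also called the same way in H1R, 20 higher and 24 lower, among them PPDPF, CPNE8, SLA, HSPA12A, SPO11, MMP9, TRBV6-5, ELOVL7 and MME. Independent lists would share 0.122 higher and 0.146 lower probe sets, and simulated unchanged groups with shared WT arrays shared 0. Such groups hold hardly any calls and the first value leaves out the shared arrays, so neither measures what the WT arrays add. Part of the excess may come from them. Across the probe sets, the log2 fold changes of both comparisons correlated at 0.598 (Spearman 0.485) where the simulation gave 0.406, and genes are not independent replicates. Their covariance was 0.271 against 0.0902 simulated, a difference of 0.181. With no array in common, replicate 1 of H1R over replicate 1 of WT against the array labelled H1L over replicate 2 of WT, the correlation was 0.341, and for the converse pairing 0.309. The Spearman correlation of the first pairing was 0.224. In these pairings 53.3% and 57% of all probe sets had the same sign. With all arrays the share was 64.1%, close to the 63.3% of the simulation. With the day as block, 106 were called the same way, and without replicate 1 of WT 2 were, without replicate 2 of WT 27, without replicate 1 of H1R 94 and without replicate 2 of H1R 91.

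**Figure D2:**
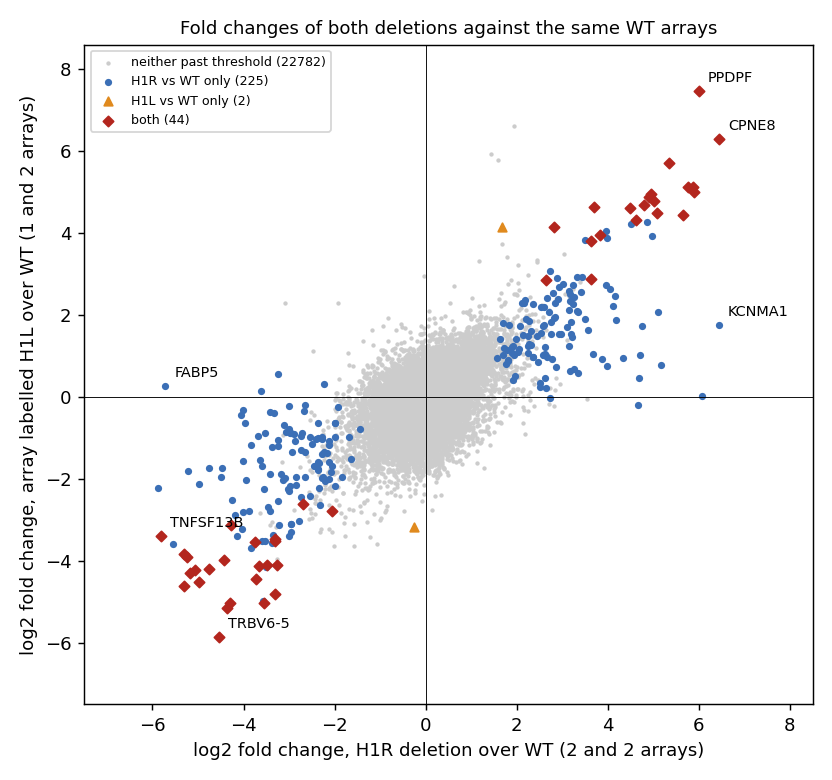
Log2 fold change of each tested probe set in H1R over WT (horizontal) against the array labelled H1L over WT (vertical), with red diamonds for the 44 called in both, blue points for those called for H1R but not for H1L and orange triangles for the converse. The called probe sets lie mainly in the lower left and upper right corners, with FABP5 near 0 on the vertical axis.

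Genes of some whole chromosomes shifted together between arrays. Relative to the median gene, the genes of chromosome 11 (151 tested) had a median log2 ratio of 0.47 in H1R over WT on the first day, 0.45 on the second day and 0.40 for the array labelled H1L over replicate 2 of WT. Chromosome 9 (163 genes) gave 0.49, 0.29 and 0.33, and chromosome 21 (76 genes) gave -0.74, -0.32 and -0.42. On the array labelled H1L over replicate 2 of WT, chromosome 20 reached 0.68, with 97.7% of its 130 genes above the median gene. In H1R over WT, chromosome 20 gave -0.07 and 43.8% on the first day and 0.37 and 82.3% on the second. Chromosome 3 reached 0.42 on the array labelled H1L, with 87.8% of 466 genes above the median gene. The WT arrays also differed from each other: replicate 2 over replicate 1 gave -0.42 for chromosome 10, -0.36 for chromosome 12, -0.35 for chromosome 20 and -0.37 for chromosome 21. Chromosome 12 gave -0.41 in H1R over WT on the first day and 0.37 on the second. Apart from that of chromosome 20 in H1R over WT on the first day, each of these medians lay farther from 0 than all 10000 random lists matched on signal. PPDPF, SPO11 and MMP9 lie on chromosome 20. When chromosome medians were removed, the log2 fold change of SPO11 on the array labelled H1L went from 4.95 ± 0.57 to 4.42 ± 0.65 (limma adjusted p from 0.021 to 0.072). That of MMP9 went from 4.15 ± 0.55 to 3.62 ± 0.63 (limma adjusted p from 0.038 to 0.14). With the smaller fold and the larger error neither passed. SNX7 on chromosome 8, at -4.44 ± 0.62 before and -4.38 ± 0.63 after, no longer passed either.

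**Figure D3:**
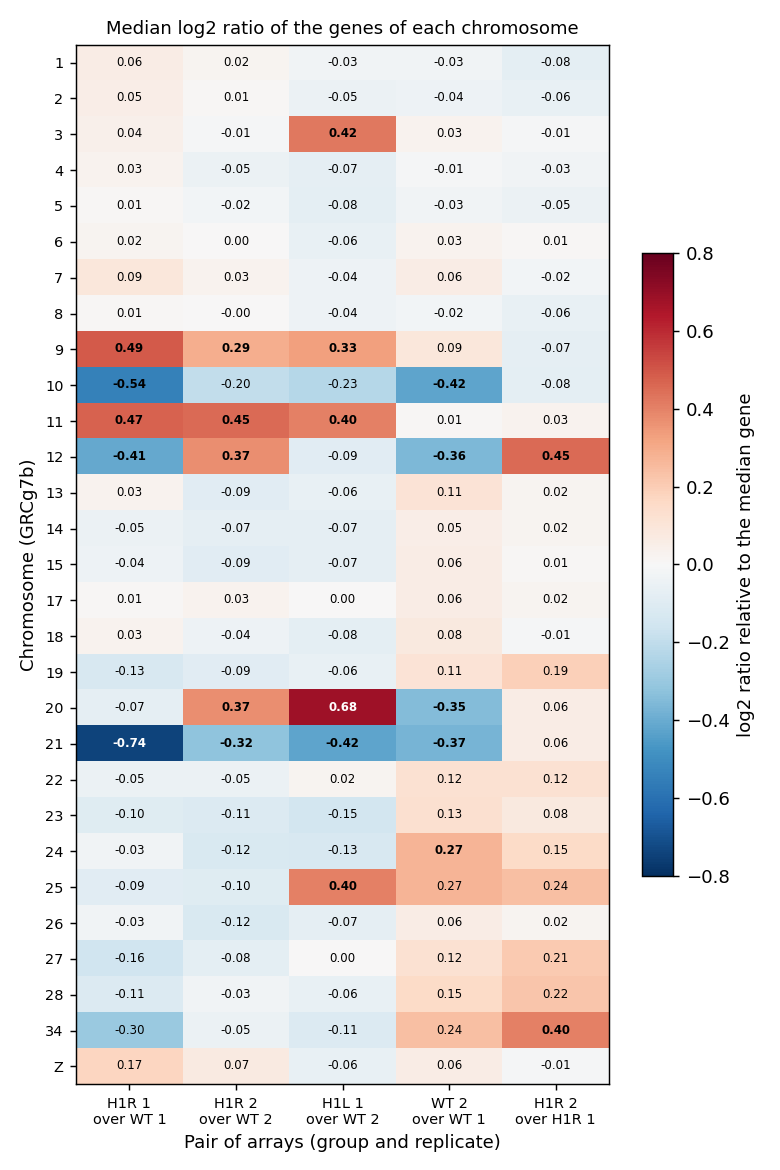
Median log2 ratio of the genes of each chromosome (GRCg7b) for 5 pairs of arrays, relative to the median gene, with red for higher and blue for lower and bold values where the shift passed. Chromosomes 9 and 11 are red and chromosome 21 is blue in all 3 pairs of a labelled deletion over WT, chromosome 21 also in WT 2 over WT 1, while chromosome 12 has opposite colours in H1R over WT on the 2 days.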

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

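The tests on scaling, labelling, small chromosomes and copy number were chosen after the shifts had been seen.

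FABP5 stood out because its level differed between the labels in a direct test: its log2 fold change on the array labelled H1L over H1R was fitted as 5.99 ± 0.39, at least 39.1-fold (limma adjusted p = 0.0075). Leaving out replicate 1 of WT ends the call of this comparison, with 0 probe sets past limma's threshold and 1122 at an unadjusted p under 0.05. The WT arrays enter this comparison only through its error: the fold of FABP5 stayed at 5.99 and its limma adjusted p became 0.054, within a range of 0.00051 to 0.13 over all alternatives.

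Chromosome 12 stood out because its genes moved in opposite directions on the 2 days: the median log2 ratio of H1R over WT was -0.41 on the first day and 0.37 on the second, a difference that was not tested. It belongs to a wider pattern in which genes of whole chromosomes shifted together, also between replicates of a group. In replicate 2 over replicate 1, chromosome 12 gave -0.36 for WT and 0.45 for H1R, so both groups differed between their arrays. Scaling between arrays was hardly tested, since ratios relative to the median gene already leave out a common scale. The median of chromosome 11 in replicate 2 of H1R over replicate 2 of WT stayed at 0.45 after quantile normalization, an outcome close to fixed. In the same pair, chromosomes 13, 14, 15, 17, 18 and 19 had a median shift of -0.08, which argues against a labelling bias common to all small chromosomes. That set leaves out chromosomes 9 (0.29), 12 (0.37), 20 (0.37) and 10 (-0.20). It therefore cannot decide on a bias of only some small chromosomes as the cause of the chromosome 11 shift. A bias of the smallest chromosomes between days stays open. In replicate 2 over replicate 1 of WT, chromosome 24 shifted by 0.27 and the others numbered 22 or higher had a median of 0.13. Among these others, chromosome 25 also gave 0.27 and the lowest was chromosome 26 with 0.06. In replicate 2 over replicate 1 of H1R, chromosomes numbered 22 or higher lay between 0.02 (chromosome 26) and 0.40 (chromosome 34). These values between days go with such a bias without deciding on it. Chromosome 25 was also called shifted on the array labelled H1L over replicate 2 of WT, with a median of 0.40 and 88% of its genes above the median gene. Both arrays are of the second day by their date code, so a bias between days cannot account for that shift. In that pair the other chromosomes numbered 22 or higher were not called and lay between -0.15 (chromosome 23) and 0.02 (chromosome 22). A difference in chromosome copy number between the cells is a candidate explanation, and the lower share of chromosome 11 genes above the median gene in the pairs of H1R over WT was 82.1%, though this share follows in part from the shift that prompted the test and DNA content was not analysed here. The deletions themselves stay open as an untested explanation of chromosomes 9, 10, 11 and 21. Of these, chromosomes 10 and 21 also differed between the WT arrays (-0.42 and -0.37).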

How the results depend on the processing

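The chromosome alternative was chosen after the data were seen. Of 49 named values past the threshold, 21 kept it in every setting that leaves out no array and 24 when any array was left out. Over those settings 587 of 663 named values kept their direction and side of the threshold, 69 no longer passed, 7 newly passed and 0 reversed. With an array left out, 233 of 282 kept both, 36 no longer passed, 10 newly passed and 3 reversed. The reversals were HIST1H111L in H1R against WT, 0.21 without replicate 2 of WT and 0.53 without replicate 1 of H1R (range -0.74 to 0.53), and in H1L against H1R, -0.05 without replicate 1 of H1R (range -0.05 to 1.22). The ribosomal protein median in H1L against WT, -0.00449 after quantile normalization, had a reversed test. The cause was not tested for any of these, except where fewer arrays or probe sets were used.

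Counts of changed probe sets, 269 for H1R against WT, 46 for H1L against WT and 1 for H1L against H1R, were 854, 117 and 31 with the day as replicate block. The pairing by day kept each named call of both deletions against WT. Without a filter on dim probe sets the first 2 were 103 and 4, and without a trend the 3 were 145, 0 and 0, with 1568 and 1338 at an unadjusted p under 0.05 for the last 2. A pseudocount of 1.5 gave 27 for H1L against WT. H1L against H1R was 2 after quantile normalization and with a pseudocount of 24. Leaving out an array gave 81 to 328, 2 to 126 and 0 to 32.

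Size counts were 929, 839, 583 and 544 with a pseudocount of 24 (H1R, H1L, H1L against H1R, H1R on both days) and 1159, 1128, 875 and 679 with the stricter filter. Without a filter the first 3 were 3195, 4361 and 4087. Probe sets called the same way in both deletions were 106 with the replicate block, 25 with a pseudocount of 1.5, 4 without a filter, 0 without a trend and 2 to 94 with an array left out, and the correlation then ranged from 0.467 to 0.695.

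Lists called in H1R against WT were 1, and 2 after quantile normalization, median scaling, removal of chromosome medians or averaging of probe sets, 0 with an estimated correlation or fry, which does not compare a list with other genes, and 0 to 1 with an array left out. In H1L against WT they were 3, and 5 with the block, 1 after median scaling or averaging, 0 with an estimated correlation or fry and 2 to 4 with an array left out. In H1L against H1R they were 0, and 1 with the block, quantile normalization, removal of chromosome medians or averaging and 0 to 1 with an array left out. Signal over background limits all of this: 130 of the 269 and 33 of the 46 calls were dim in 1 group.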

Other observations

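The test of the WT difference and that of cross-hybridization were chosen after the results were seen, as were the use of FABP5 against an H1R culture and the tests with a WT or H1R array left out.

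Several genes outside the named ones were called the same way in both deletions, and are given here after their values were seen. ASB2, a subunit of a ubiquitin ligase, was higher (log2 fold change 2.65 in H1R and 2.86 for the array labelled H1L). CDR2 was lower (-2.69 and -2.61), as were ARG2, an arginase (at least 11.6-fold in H1R, log2 fold change -3.13 for the array labelled H1L), and MTHFS, an enzyme of folate metabolism (log2 fold change -3.31 in H1R, at least 11-fold for the array labelled H1L). GRIA3, a glutamate receptor subunit (at least 6.86-fold and 7.33-fold), and TMEM108 (at least 8.17-fold and 8.73-fold) were lower in both too. Reporter probe sets, 57 in number, reached at most 58.5 on any array.

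Of the 46 probe sets called for the array labelled H1L against WT, 44 were called the same way in H1R. The tables argue against the shared WT arrays as the whole cause, since the correlation of fold changes was 0.341 with no array in common. Of the shared calls with a known chromosome, 4.88% lie on chromosomes 9 and 11, also when chromosome 21 is added. Of the tested probe sets, 5.77% lie on 9 and 11. This share cannot decide on the shared shifts of chromosomes 9 and 11. Their medians reached at most 0.49, and the smallest change called for the array labelled H1L was 2.61. With all arrays, which share WT, the correlation was 0.598. It was 0.616 over probe sets with a known chromosome outside 9 and 11, and 0.613 without chromosome 21 as well. The correlation with all arrays therefore does not rest on genes of these chromosomes. The correlation with no array in common was not computed without them. A WT culture that had drifted from the parent of the mutants is a candidate explanation that cannot be told apart from an effect of both deletions, because all 44 shared calls set the mutants against the same WT cells and no other WT stock was analysed here. An effect common to loss of either variant stays open as untested.

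HIST1H111L was not lower on the array labelled H1L. The tables argue against cells like those of the WT arrays under that label: of 81 and 149 probe sets called in H1R against 1 WT array, 3.7% and 12.1% showed at least 0.5 of that log2 change on the WT array left out but 64.2% and 74.5% on the array labelled H1L, at least 60.5 percentage points more. They also argue against cells like those of the H1R arrays: of 281 and 328 probe sets called against WT from 1 H1R array, 89% and 79.3% showed at least 0.5 of the change on the H1R array left out but 63.7% and 55.5% on the array labelled H1L, at least 23.8 percentage points fewer. A separate WT or H1R culture that differs from these arrays cannot be told apart: the array differed 4-fold from replicate 2 of WT in 106 probe sets with a mean signal of at least 100 (156 from replicate 1, 33 between the WT arrays), above the limit set beforehand, and from replicate 2 of H1R in 53 (59 between the H1R arrays), within it though 93 from replicate 1 was above it and FABP5 passed in the direct test, but replicates may share a culture, so neither limit allows for what cultures differ by. Cross-hybridization could also keep the signal of 2295.3 without the gene, and probe sequences, which would decide, were not analysed here.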
